A study of Mus musculus with 6 samples.

How the data were processed

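Expression was measured by 3' digital mRNA sequencing (3'DGE), a method in which reads come from the 3' ends of transcripts, in epidermis from the back skin of E18.5 mouse embryos. Per the labels' protocols, epidermis was parted from dermis by overnight Dispase digestion and made into single cells with Accutase. The labels name different RNA kits in different fields (a Qiagen column kit for the samples and a Zymo kit in the design text), so the kit is not settled here. The 6 libraries fell into 3 wild-type (WT) libraries and 3 libraries of the genotype p63alphaKO, taken from the sample labels. Nothing in the sources used here says in so many words that the replicates of a group were separate embryos. The p-values therefore set the group difference against the spread between these libraries only.

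STAR and HTSeq are the tools, and mm10 the genome build, that the submitters' processing notes name. Their versions, the annotation used for counting and whether counting used the strand are not given in the sources used here. The deposited table is named as normalized counts, but its 6 columns each sum to between 999157 and 999401, so the deposited values are CPM, scaled by the authors to each library's total. It holds 30386 genes, of which 14023 are at 0 in all 6 libraries. The design fixed before the data were examined assumed another kind of normalized count. Its pseudocount of 1 and its minimum mean of 10 were kept and applied to CPM.

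The CPM values of each library were whole multiples of what a single read is worth, within a tolerance of 0.0055 CPM, for 100% of values, and this gave each library's reads. The totals were 2564407, 4474764 and 3174444 reads in WT replicates 1, 2 and 3, and 3539604, 3431580 and 3350442 reads in p63alphaKO replicates 1, 2 and 3. A mean of 10 CPM corresponds to between 25.7 and 44.8 reads per library. The limit that 3 reads set lay between 0.670 and 1.17 CPM. Such limits cover counting error only, since no source used here says that molecular identifiers were counted.

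The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), with genotype as the only term, two-sided, over the 7464 genes with a mean of at least 10 CPM. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg). All log2 fold changes are p63alphaKO over WT on the log2(CPM + 1) scale, which understates the change of genes at low levels. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1, so no such test could pass the threshold.

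Before the data were examined, 34 gene lists were written from textbook knowledge of epidermis, of p63, of stress responses and of the other cell types a skin sample can hold. The 30 lists with at least 3 tested members were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from these libraries and fry were run beside it. Counts of called members are given over all tested genes and adjusted over the list alone.

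The genes named were chosen by a rule fixed before the data were examined. Its first part is a set of 17 genes of p63 biology and epidermal structure. Its second part takes called genes with a mean of at least 50 CPM and no overlap between the groups, and names the 12 with the largest rise and the 12 with the largest fall. There were 23 and 41 such genes. A further part takes, from each list that was called or had a called member, up to 4 members with the smallest p, and otherwise up to 2 members with the highest level. Y-linked genes and Xist were left out of the second part. Some genes that the rule names are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

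Positions are from GENCODE mouse release 21 on mm10/GRCm38 and are 1-based. Of the 30386 gene IDs, 30271 (99.6%) were found there, and 7462 of the 7464 tested genes. Exons that overlap a gene on the other strand were looked up for each named gene. Among the called ones, Krt6a, Krt6b, Plet1, Fgfr1, Fn1, Hspa1a, Meg3, Neb, Tnnc2 and Ttn overlap such a gene. So do some named genes without a call, among them Krt5, Krt10, Dsp, Fgfr3, Il1a, Zeb2, Slc2a1, Ndrg1, Cdkn1a, Lama3, Notch1, Hmgcs1, Pmel and Ncam1. The values of all these genes are uncertain where counting did not use the strand.

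The steps were tested on simulated data made from these libraries' means and depths for this comparison, with 200 of 7399 genes changed. Of the changed genes, 2.08% were called at a 1.5-fold change, 46.9% at 2-fold, and 100% at 4-fold and at 8-fold. Among the calls, 8% were unchanged genes. A list raised by 0.5 log2 units reached an adjusted p of 5.2e-13, and 0 of 18 lists without a changed member were called. The simulated genes were drawn independently of one another, so these list results do not cover lists whose members move together. In the real libraries the estimated correlation was 0.918 for late cornified envelope genes, 0.856 for small proline-rich genes and 0.990 for erythroid genes.

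The alternatives fixed in advance were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50 CPM, TMM and upper quartile factors (edgeR 4.0.16) and quantile normalization of the deposited values, robust moderation, library weights, the replicate number as a block, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, leaving out each library in turn, an adjusted p under 0.1, a 2-fold minimum, and the other list tests. Chosen after seeing the data were a dermal score as a covariate (the mean log2 level of the tested fibroblast and dermis list members), embryo sex as a covariate, leaving out the ribosomal RNA locus Gm42418, and leaving out together the members of the lists for other cell types, heat shock and immediate early genes, mitochondrially encoded transcripts and Y-linked genes.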

Results

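The p63 transcription factor, encoded by Trp63, is made in isoforms that differ at their carboxy terminus, of which the alpha forms are the longest. The study compared back skin epidermis from E18.5 mouse embryos between wild type (WT, 3 libraries) and a genotype labelled p63alphaKO (3 libraries), and its title places the comparison in the question of how far epidermal homeostasis depends on the p63 isoform. How the allele was made is not given in the sources used here. Expression was read from the 3' ends of mRNAs, at 2564407, 4474764 and 3174444 reads in WT replicates 1, 2 and 3 and 3539604, 3431580 and 3350442 reads in p63alphaKO replicates 1, 2 and 3. Levels are given in CPM as mean ± SD with n = 3 per group, and log2 fold changes are p63alphaKO over WT with their standard error (SE).

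In p63alphaKO epidermis, the Trp63 gene itself, Krt77 and the stress keratins Krt6a and Krt6b were higher, the basal keratin Krt15 was lower, and the main basal and suprabasal keratins Krt5, Krt14, Krt1 and Krt10 did not pass the test. Of 7464 genes tested with limma, 123 changed, 35 of them higher and 88 lower. Many of the genes lower in p63alphaKO were markers of dermis, muscle and blood, and 25 of the 88 belonged to lists of non-epidermal cells. At least 2-fold changes were found in 27 of the higher and 81 of the lower genes. The values of the groups did not overlap for 1569 genes (21%), against 10% by chance. Without p63alphaKO replicate 1, 2 or 3 the count of changed genes was 46, 67 or 37, with 6, 6 or 3 of them higher, and without WT replicate 1 it was 186, with 90 higher. Without WT replicate 2 there were 56 higher genes. Rescaling moved the median log2 fold change of all tested genes from -0.085 to 0.018 with TMM factors and to 0.048 with upper quartile factors, and the share of lower genes among the calls went from 71.5% to 58.0% and 48.1%.

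**Figure D1:**
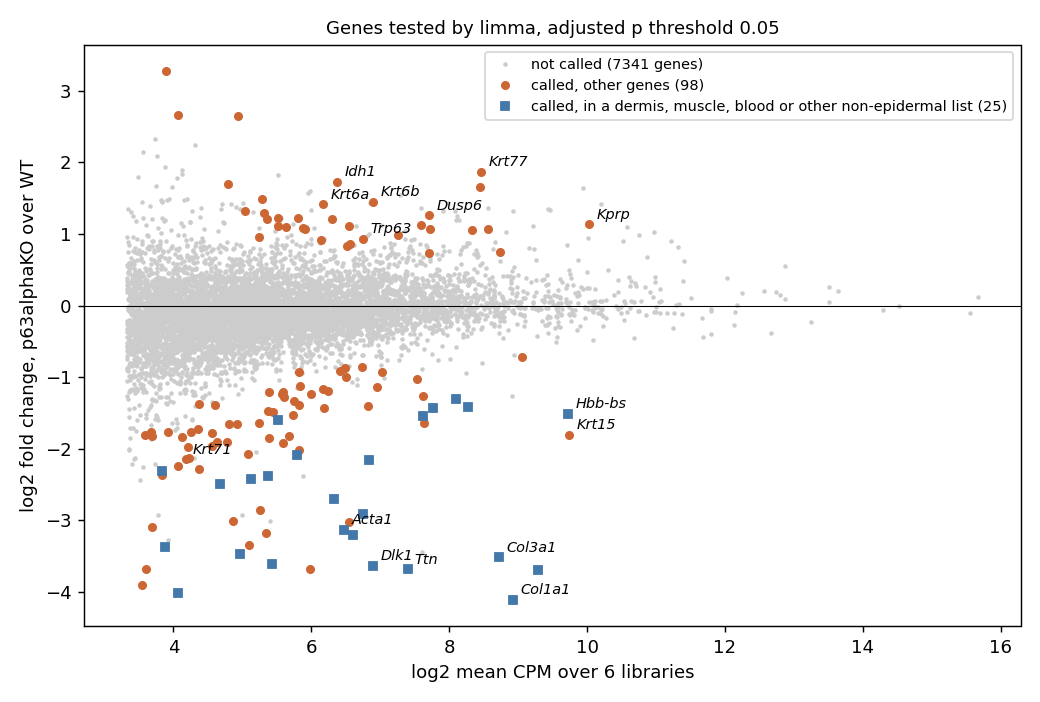
Log2 fold change (p63alphaKO over WT) against log2 mean CPM over the 6 libraries for each of the 7464 genes tested. Grey points were not called, and the 123 called genes are in orange or, for the 25 in lists of dermis, muscle, blood and other non-epidermal cells, in blue squares, all of which lie below 0.

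The libraries of the p63alphaKO group resembled one another more than those of the WT group did. Pearson's r of log2 values over tested genes was between 0.956 and 0.966 for pairs of p63alphaKO libraries, between 0.918 and 0.925 for WT pairs, and between 0.887 and 0.937 for pairs of different genotype. The first principal component of the 500 most variable genes held 49.3% of their variance and had all 3 WT libraries on its negative side and all 3 p63alphaKO libraries on its positive side.

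Trp63 mRNA was higher in p63alphaKO. Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102, plus strand, mm10) was at 74.3 ± 11.9 CPM in WT and 142 ± 5.15 CPM in p63alphaKO, a log2 fold change of 0.93 (SE 0.19, adjusted p = 0.0192, 1.91-fold), and each p63alphaKO library lay above each WT library. The count is per gene, so it cannot tell isoforms apart and does not check the loss of the alpha forms. Of the 8 annotated coding transcripts, 4 end within 50 bases of the most common 3' end. Which of these encode alpha forms was not looked up. The value was 0.93, 0.91 and 0.96 without p63alphaKO replicate 1, 2 or 3, with adjusted p of 0.0998, 0.0971 and 0.0854, so the call needed all 3 p63alphaKO libraries. The p53 family members Trp53 and Trp73 showed no called change. Trp53 was at 24.3 ± 6.44 CPM in WT and 21.5 ± 1.31 CPM in p63alphaKO (adjusted p = 0.866), and Trp73, at 6.32 ± 1.26 and 8.87 ± 6.25 CPM, was under the minimum for testing.

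Genes known to be bound or driven by p63 in epidermis did not move as a group. Of 36 tested members of that list, 18 had positive and 18 negative fold changes, only Trp63 was called, and the list's adjusted p was 0.347 by camera (0.873 with an estimated correlation). The desmosomal cadherin Dsc3 was at 330 ± 84.1 CPM in WT and 216 ± 17.9 in p63alphaKO (log2 fold change -0.58, adjusted p = 0.162). Zfp750, a regulator of terminal differentiation, had a value of -0.55 (adjusted p = 0.211), and the integrin gene Itga3 a value of 0.58 (adjusted p = 0.279). Perp had a log2 fold change of -0.074 (adjusted p = 0.870), and the growth factor receptors Fgfr2 and Fgfr3, known as p63 targets, values of -0.054 and -0.65 (adjusted p = 0.961 and 0.292).

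Among basal keratinocyte genes, Krt15, a keratin of basal cells, was the called change. Krt15 (chromosome 11, 100131758 to 100135928, minus strand) fell from 1347 ± 530 CPM in WT to 361 ± 18.6 CPM in p63alphaKO, a log2 fold change of -1.80 (SE 0.25, adjusted p = 0.00164, 3.49-fold lower), and it was called without any 1 of the 6 libraries. Krt5 and Krt14, the keratin pair that defines the basal layer, were at 1503 ± 426 and 1791 ± 633 CPM in WT and 1821 ± 197 and 2263 ± 264 CPM in p63alphaKO, with log2 fold changes of 0.31 and 0.39 (adjusted p = 0.480 and 0.417). Without WT replicate 1 these were 0.067 and 0.11, and the highest with 1 library left out were 0.49 and 0.64. The basal list of 19 genes, 13 positive and 6 negative, had a median log2 fold change of 0.27 and was not called (adjusted p = 0.0675, 0.312 with an estimated correlation). Adjusted over the list alone, 2 members were higher and 3 lower. The median was 0.11 without WT replicate 1, and the list was called in 2 of 22 other settings, among them no filter (adjusted p = 0.0234). Igfbp2 had a value of -1.29 (adjusted p = 0.0959) and the laminin chain Lama3 one of 0.76 (adjusted p = 0.135). Postn, also a member of the fibroblast and dermis list, had a value of -0.69 (adjusted p = 0.146).

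**Figure D2:**
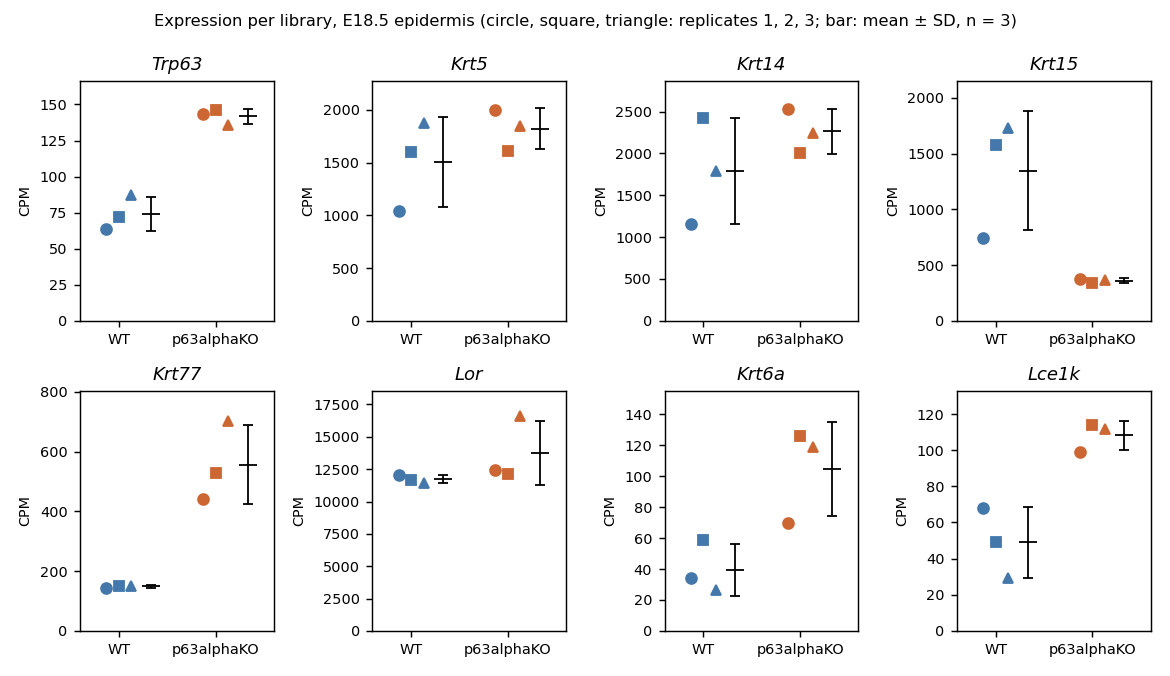
CPM of 8 genes in each library, with replicates 1, 2 and 3 as circle, square and triangle and the group mean ± SD (n = 3) beside them. The values of WT and p63alphaKO do not overlap for Trp63, Krt15, Krt77, Krt6a, Lce1k and Lor, and they overlap for Krt5 and Krt14.

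In the spinous list, Krt77, a suprabasal keratin, stood apart. Krt77 (chromosome 15, 101858731 to 101869705, minus strand) rose from 149 ± 4.56 CPM in WT to 557 ± 133 CPM in p63alphaKO, a log2 fold change of 1.87 (SE 0.18, adjusted p = 0.000219, 3.65-fold), and was called without any 1 of the libraries. Krt1 and Krt10, the keratin pair of the spinous layer, were at 23979 ± 5967 and 50275 ± 12157 CPM in WT, with log2 fold changes of -0.011 and -0.10 (adjusted p = 0.989 and 0.871). The list as a whole was not called (16 tested, 1 higher, adjusted p = 0.577 by camera, 0.670 with an estimated correlation). Its median was -0.060 and its mean 0.062, and camera's direction was that of the mean. Hes1, a Notch effector, had a value of -0.37 (adjusted p = 0.446) and Dsg1a one of -0.29 (adjusted p = 0.463).

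In 2 gene families of the cornified envelope, the protein shell of dead surface cells, all tested members had positive fold changes, but only Lce1k was called over all genes. The mean log2 level of the small proline-rich family overlapped between the groups, at 7.14 in WT replicate 2 and 6.88 in p63alphaKO replicate 1. All 19 tested late cornified envelope genes had positive fold changes, with a median of 1.17 on the log2 scale (2.24-fold). Of these, 1 was called over all genes and 19 were called adjusted over the list alone, and the list was called by camera (adjusted p = 1.6e-19) but not with an estimated correlation (adjusted p = 0.291). Lce1k (chromosome 3, 92806291 to 92807891, minus strand) rose from 48.9 ± 19.5 to 108 ± 8.17 CPM (log2 fold change 1.21, adjusted p = 0.0316), and Lce3c, Lce1f and Lce1h had values of 1.32, 1.34 and 1.36 (adjusted p = 0.0547, 0.0556 and 0.0560). The 9 tested small proline-rich genes were all positive, with a median of 1.41, 0 called over all genes and 6 adjusted over the list alone (camera adjusted p = 4.9e-07, 0.312 with an estimated correlation). Sprr1b had a value of 1.64 (adjusted p = 0.0959) and Sprr2e one of 1.59 (adjusted p = 0.0519). Kprp, a keratinocyte proline-rich protein gene (chromosome 3, 92823074 to 92827247, minus strand), rose from 677 ± 291 to 1418 ± 218 CPM (log2 fold change 1.14, adjusted p = 0.0260). WT replicate 3 decided much of the size: without it the list medians were 0.59 for late cornified envelope genes and 0.68 for small proline-rich genes. Members of these families are near-identical copies, so reads shared between them make single values uncertain, and the calls of Lce1k and Kprp were lost without p63alphaKO replicate 1, 2 or 3 and without WT replicate 2 (adjusted p from 0.0507 to 0.181 for Lce1k and from 0.0629 to 0.196 for Kprp).

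The other genes of the granular and cornified layers differed less. That list of 29 tested genes had a median log2 fold change of 0.20, with 18 positive, 0 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000622, 0.312 with an estimated correlation, and 0.0627 after quantile normalization), and the median was 0.076 without p63alphaKO replicate 3. Lor and Flg, encoding the bulk proteins of the granular layer, were at 11743 ± 315 and 20556 ± 4334 CPM in WT and had values of 0.21 and -0.059 (adjusted p = 0.590 and 0.925), and Ivl one of 0.038 (adjusted p = 0.944). Rptn, Cnfn, Crct1 and Asprv1 had values of 1.15, 0.63, 0.63 and 0.55 (adjusted p = 0.0547, 0.0669, 0.132 and 0.123). Barrier lipid genes had a median of 0.22 over 25 tested genes, 19 of them positive and 0 called either way (camera adjusted p = 0.000138, 0.291 with an estimated correlation). Cers3, a ceramide synthase, and Abca12, a lipid transporter of lamellar granules, had values of 0.66 and 0.58 (adjusted p = 0.0998 and 0.134), Sdr9c7 one of 0.50 (0.175) and Nipal4 one of 0.70 (0.183). The 22 cholesterol synthesis genes, among them Hmgcs1 (-0.033) and Msmo1 (0.017), had a median of -0.030 and 0 calls (camera adjusted p = 0.892, with the opposite sign).

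Cell adhesion genes showed no single called member. Desmosome genes had a median log2 fold change of -0.10 (14 tested, adjusted p = 0.709), with Dsp at -0.27 (adjusted p = 0.458) and Cdsn at 0.33 (adjusted p = 0.344). Adherens and tight junction genes had a median of 0.089 (15 tested, 9 positive, 1 called adjusted over the list alone, camera adjusted p = 0.0197, 0.291 with an estimated correlation, and 0.0947 after quantile normalization). In that list Cldn4 had a value of 0.71 (adjusted p = 0.0725), Cdh1 one of 0.50 (0.146) and F11r one of 0.72 (0.184). Hemidesmosome and basement membrane genes had a median of 0.20 (18 tested, 13 positive, 0 called either way, camera adjusted p = 0.00264, 0.312 with an estimated correlation). The laminin chains Lama3 and Lamb3 had values of 0.76 and 0.58, and neither passed the test (adjusted p = 0.135 and 0.304). The junction median was 0.047 without WT replicate 3, 0.019 without p63alphaKO replicate 1 and 0.21 without p63alphaKO replicate 3. Without WT replicate 1 the hemidesmosome median was 0.040 and its adjusted p 0.0509, and the call was also lost with a minimum mean of 50 CPM (adjusted p = 0.0570), while without WT replicate 3 the median was 0.33.

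Most tested stress keratins and alarmins, which keratinocytes switch on after injury, had positive fold changes in p63alphaKO, while the list's share of counts hardly differed. That share was 1.37% ± 0.106 in WT and 1.42% ± 0.0736 in p63alphaKO. Sprr1b is a member of both this list and the small proline-rich list. Of 16 tested genes 14 were positive, with a median log2 fold change of 0.84, 2 called over all genes and 8 adjusted over the list alone (camera adjusted p = 6.0e-08, 0.291 with an estimated correlation). Krt6a (chromosome 15, 101689910 to 101694307, minus strand) rose from 39.6 ± 16.8 to 105 ± 30.4 CPM (1.41, adjusted p = 0.0249). Krt6b (101676023 to 101680287 on the same strand) rose from 66.7 ± 36.0 to 172 ± 42.0 CPM (1.45, adjusted p = 0.0257). The cytokine gene Il1a had a value of 1.45 at low level (7.40 ± 3.10 against 21.2 ± 2.91 CPM, adjusted p = 0.0669). Krt6a and Krt6b are near-identical copies and each overlaps an annotated gene on the opposite strand, so how reads divide between them is uncertain. The median was 0.43 without WT replicate 3, and the calls of Krt6a and Krt6b were lost without p63alphaKO replicate 3 (adjusted p = 0.182 and 0.196), without p63alphaKO replicate 2 (0.101 and 0.0892) and without WT replicate 1 (0.0528 and 0.0586).

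In FGF and EGF receptor signalling, Dusp6, a phosphatase induced by ERK activity, rose and Fgfr1 fell. Dusp6 (chromosome 10, 99263231 to 99267489, plus strand) went from 129 ± 55.5 to 288 ± 19.3 CPM (log2 fold change 1.26, SE 0.27, adjusted p = 0.0318), and Fgfr1, a receptor gene also active in dermis, at 30.3 ± 7.62 CPM in WT, fell by 1.38 (adjusted p = 0.0448). The fibroblast and dermis markers, described further on, were lower in the same libraries as Fgfr1. The list of 19 tested genes had a median of 0.36, with 15 positive, and adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.000130, 0.291 with an estimated correlation). The EGF family ligand Epgn had a value of 1.57 (adjusted p = 0.0652) and Fgf1 one of 1.36 (adjusted p = 0.112). The list median lay between 0.26 and 0.58 with 1 library left out, and was highest without WT replicate 1. Dusp6 had a value of 0.84 without WT replicate 3. The Dusp6 call was lost without p63alphaKO replicate 1, 2 or 3 (adjusted p = 0.119, 0.0897 and 0.168), and that of Fgfr1 without those (0.118, 0.0616 and 0.196) and without WT replicates 1 and 3 (0.0911 and 0.0914).

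The remaining genes with the largest rises by the naming rule, which takes called genes with a mean of at least 50 CPM and no overlap between the groups, belonged to metabolism, signalling and genes of less known function. Idh1, the cytosolic isocitrate dehydrogenase (chromosome 1, 65158616 to 65186500, minus strand), rose from 39.1 ± 16.6 to 127 ± 32.1 CPM (1.73, adjusted p = 0.00687). Plet1, a surface protein gene, rose from 186 ± 101 to 512 ± 90.1 CPM (1.65, adjusted p = 0.0316). Its value was 1.05 without WT replicate 3. Its exons overlap those of the antisense gene Plet1os, so the 2 cannot be told apart without strand. Cecr2 rose by 1.23, the carboxypeptidase gene Cpa4 by 1.12, 2810474O19Rik by 1.11 and Pfkfb3, a regulator of glycolysis, by 1.08 (adjusted p = 0.0272, 0.0492, 0.00849 and 0.0133). Among the 12 genes with the largest rises by that rule, Krt77 was the only 1 called without each of the 6 libraries in turn. Leaving out p63alphaKO replicates 1, 2 and 3 ended 9, 9 and 10 of the 12 calls, and leaving out WT replicates 1, 2 and 3 ended 2, 3 and 1. The adjusted p of these lost calls went from 0.0507 to 0.268, and Cpa4 had a value of 0.75 without WT replicate 3. Glycolysis and hypoxia genes had a median of 0.060 over 23 tested genes (camera adjusted p = 0.0231, 0.418 with an estimated correlation), and 3 were called adjusted over the list alone. Egln3, an oxygen-sensing hydroxylase, rose from 158 ± 6.61 to 262 ± 8.21 CPM (0.73, adjusted p = 0.0313), while Slc2a1, Ndrg1 and Adm had values of 0.86, 0.88 and 1.19 (adjusted p = 0.0544, 0.0869 and 0.154). Adm was at 0.53 without WT replicate 3 and 1.73 without WT replicate 1 (adjusted p = 0.304 and 0.0213). The glycolysis and hypoxia median went from -0.057 without p63alphaKO replicate 1 to 0.15 without p63alphaKO replicate 3, and moved by over 1.5 times with each left-out library but WT replicate 1. Its call was lost without WT replicate 3 (adjusted p = 0.165) or p63alphaKO replicate 1 (0.0963) and after quantile normalization (0.0731), and Egln3 was not called without p63alphaKO replicate 1, 2 or 3 (adjusted p = 0.117, 0.122 and 0.160).

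Krt71 and Krt25, both keratins of the hair follicle's inner root sheath, were lower in p63alphaKO. Krt71 fell from 30.3 ± 10.2 to 5.89 ± 1.02 CPM (log2 fold change -2.15, adjusted p = 0.00731) and Krt25 from 42.6 ± 8.71 to 13.2 ± 5.21 CPM (-1.66, adjusted p = 0.0140). The hair keratin and follicle sheath list (8 tested) had a median of -0.73, with 2 called and, adjusted over the list alone, 4 lower and 1 higher (camera adjusted p = 0.0675, 0.312 with an estimated correlation). Foxn1, a regulator of hair shaft differentiation, had a value of -1.28 (adjusted p = 0.0718) and Krt79, a keratin of the upper follicle, one of 0.88 (adjusted p = 0.200), which was 0.57 without WT replicate 1 and 1.38 without WT replicate 3 (adjusted p = 0.350 and 0.00171). Wnt and hair placode genes had a median of -0.14 and 0 called over all genes (15 tested, camera adjusted p = 0.732 with the opposite sign), with Sox9 at 0.63 (adjusted p = 0.0696) and Wnt4 at -0.15 (adjusted p = 0.797). With 1 library left out the Wnt median lay between -0.32 and 0.19, and without WT replicate 3 the list was called (adjusted p = 0.0453). The Krt25 call was lost without p63alphaKO replicate 1 or 3 (adjusted p = 0.0744 and 0.0816), and the fibroblast and dermis markers, described further on, were lower in the same libraries.

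Genes of TGF-beta signalling and of the mesenchymal state were lower for 3 of 17 tested members. Fn1, encoding fibronectin, fell from 67.2 ± 3.75 to 28.1 ± 4.18 CPM (-1.24, adjusted p = 0.00898), Mmp2 fell with a value of -1.78 and Id2 with -1.21 (adjusted p = 0.0229 and 0.0456), and Zeb2 had a value of -1.54 (adjusted p = 0.0523). The list was not called (median -0.15, camera adjusted p = 0.311, 0.464 with an estimated correlation), and 5 members were lower adjusted over the list alone. Dermal fibroblasts also express Fn1, Mmp2 and Zeb2, and the fibroblast and dermis markers, described further on, were lower in the same libraries. Without p63alphaKO replicate 3 the adjusted p was 0.0539 for Fn1, 0.138 for Mmp2 and 0.146 for Id2. Id2 was not called without any of the other libraries except WT replicate 3 (adjusted p between 0.0910 and 0.160), Fn1 not without p63alphaKO replicate 1 (0.0575), and Mmp2 not without WT replicate 1 (0.0609) or p63alphaKO replicate 2 (0.0814). Notch pathway genes had a median of -0.13 (9 tested, camera adjusted p = 0.577), with Notch1 at 0.12 (adjusted p = 0.838). With 1 library left out the TGF-beta median lay between -0.35 and -0.038 and the Notch median between -0.29 and -0.030.

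Of the stress-response genes, heat shock and immediate early genes moved both ways. Hspa1b and Hspa1a, the inducible HSP70 pair, fell by 1.02 and 0.93 on the log2 scale (251 ± 67.8 to 120 ± 10.4 CPM and 172 ± 48.3 to 88.1 ± 9.66 CPM, adjusted p = 0.0192 and 0.0412). Fos fell by 0.72 (661 ± 55.4 to 402 ± 53.9 CPM, adjusted p = 0.0335), while Ier3 rose by 1.05 (212 ± 58.0 to 429 ± 21.3 CPM, adjusted p = 0.0159). The list of 27 had 1 higher and 3 lower members and was not called (median 0.032, camera adjusted p = 0.936 with the opposite sign). With 1 library left out its median lay between -0.18 and 0.17, and without WT replicate 3 it was called (adjusted p = 0.0269). Each of these 4 calls was lost without any 1 of the p63alphaKO replicates (adjusted p from 0.0744 to 0.208), that of Fos also without WT replicate 2 (0.0817), and that of Hspa1a without WT replicate 2 or 3 (0.0533 and 0.0881). Hspa1a and Hspa1b are near-identical copies whose reads cannot be divided with certainty.

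Proliferation, p53 target, interferon and protein-folding genes gave 0 calls. The 30 tested proliferation genes had a median of -0.20, with Top2a at -0.12 and Hmgb2 at -0.29 (camera adjusted p = 0.269). Leaving out 1 library moved that median between -0.30 and -0.015. The p53 family target list had a median of -0.051 and a mean of 0.12 (15 tested, camera adjusted p = 0.0675, 0.418 with an estimated correlation). Camera's direction was that of the mean. Cdkn1a was at 0.27 (adjusted p = 0.421). Interferon response genes had a median of -0.14 (5 tested, camera adjusted p = 0.892 with the opposite sign), with B2m at 0.44. Unfolded protein and integrated stress response genes had a median of -0.051 (21 tested, camera adjusted p = 0.709 with the opposite sign), with Hspa5 at 0.35 and Calr at -0.043. Simple epithelial and periderm genes had a median of 0.077 and a mean of -0.039 (6 tested, adjusted p = 0.671), with Sfn at 0.28 and Krt17 at 0.10. The 6 tested mitochondrially encoded transcripts were all negative with a median of -0.38 (0 called either way, camera adjusted p = 0.00458, 0.312 with an estimated correlation), mt-Cytb and mt-Nd4 standing at 4031 ± 333 and 7420 ± 1480 CPM in WT against 3069 ± 379 and 5645 ± 429 CPM in p63alphaKO, and mt-Nd5 and mt-Nd2 at -0.39 and -0.44.

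**Figure D3:**
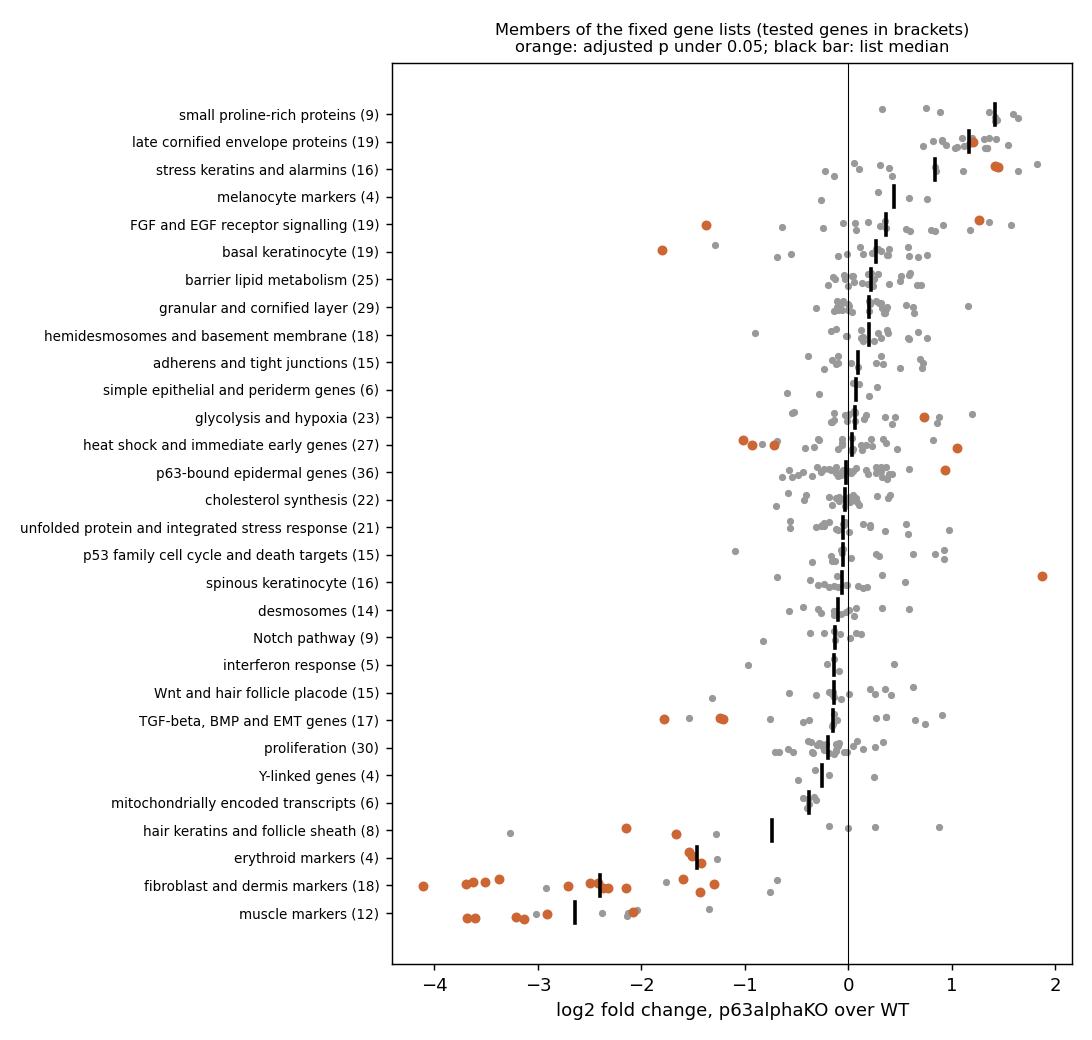
Log2 fold change (p63alphaKO over WT) of each tested member of the 30 gene lists, with the number of tested members in brackets and the list median as a black bar. Members called over all genes are in orange, and the fibroblast and dermis, muscle and erythroid lists lie wholly below 0 while the late cornified envelope and small proline-rich lists lie wholly above it.

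Markers of dermis, muscle and blood were lower in p63alphaKO preparations. Of the 12 genes with the largest falls by the naming rule, all but Meg3 and Neb belonged to the dermis and muscle lists, while the blood genes fell less. Together the fibroblast and dermis markers took 0.481% ± 0.189 of the counts in WT and 0.0835% ± 0.0262 in p63alphaKO. All 18 tested members were negative, 14 were called and 18 adjusted over the list alone, with a median log2 fold change of -2.40 (camera adjusted p = 5.9e-28, 0.291 with an estimated correlation). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042, plus strand), fell from 918 ± 440 to 56.6 ± 42.6 CPM (-4.11, SE 0.41, adjusted p = 0.000219). Col1a2, Dlk1, Col3a1, Fstl1, Col6a3 and Dcn fell with log2 fold changes of -3.70, -3.63, -3.51, -2.71, -2.15 and -1.43, and so did the noncoding RNA gene Meg3, in none of the lists, with -3.02 (adjusted p from 0.000219 to 0.00687). Muscle markers took 0.141% ± 0.155 of counts in WT and 0.0110% ± 0.00323 in p63alphaKO. All 12 tested were negative, 6 were called and 11 adjusted over the list alone, with a median of -2.64 (camera adjusted p = 1.7e-11, 0.291 with an estimated correlation) and one of -1.90 without WT replicate 2. That library held 0.320% muscle counts, against 0.0517% and 0.0511% in WT replicates 1 and 3. Titin (Ttn) fell from 321 ± 378 to 15.6 ± 8.16 CPM (-3.68), and Neb (a muscle gene outside the list), Myl1, Tnnc2, Acta1, Tnnt3 and Mylpf fell too, with log2 fold changes of -3.67, -3.61, -3.21, -3.13, -2.91 and -2.08 (adjusted p from 0.00124 to 0.0480 for these 7 genes). Of the 4 tested erythroid genes 3 were called and 4 adjusted over the list alone, with a median of -1.47 (camera adjusted p = 1.9e-05, 0.291 with an estimated correlation). The globin genes Hbb-bs, Hbb-bt and Hba-a2 fell, with values of -1.51, -1.54 and -1.42 (adjusted p = 0.0314, 0.0272 and 0.0494), and Hba-a1 had a value of -1.27 (adjusted p = 0.0505). Of these 12 genes with the largest falls, 7 were called without each library in turn, and 3, 1 and 4 calls were lost without p63alphaKO replicates 1, 2 and 3. The genes concerned were Ttn, Neb, Tnnc2, Tnnt3 and Col6a3, with adjusted p from 0.0541 to 0.182 and log2 fold changes from -3.62 to -1.76. Without WT replicate 2, Tnnc2 was at -2.08 and Tnnt3 at -1.72. Myl1 and Mylpf were not called without p63alphaKO replicate 1 (adjusted p = 0.0602 and 0.108), nor Mylpf without p63alphaKO replicate 3 (0.0766). The globin calls were lost without WT replicate 1 or p63alphaKO replicate 1 or 2, with Hbb-bs at -1.11 without p63alphaKO replicate 1, and that of Hba-a2 also without WT replicate 3 (adjusted p = 0.0671). Erythroid markers took 0.264% ± 0.0771 of counts in WT and 0.106% ± 0.0631 in p63alphaKO. Their share was 0.177% in p63alphaKO replicate 3, against 0.191% in WT replicate 2. In p63alphaKO replicates 1 and 2 it was 0.0560% and 0.0857%. Near-identical globin copies share reads.

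**Figure D4:**
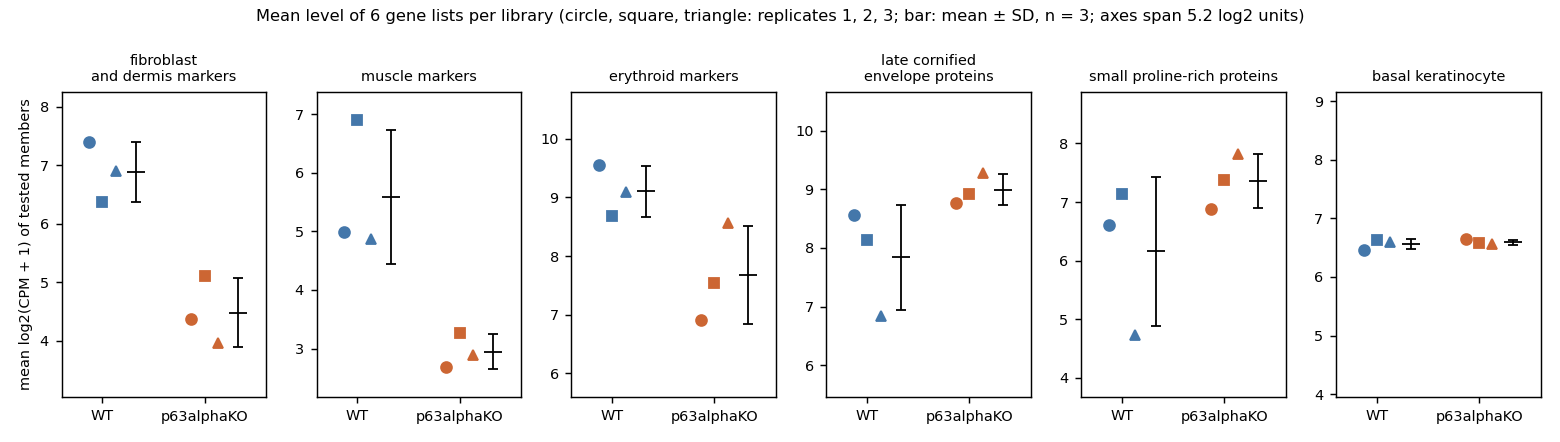
Mean log2(CPM + 1) of the tested members of 6 lists in each library, with replicates 1, 2 and 3 as circle, square and triangle and the group mean ± SD (n = 3) beside them. All axes span the same range, WT replicate 3 is lowest for the late cornified envelope and small proline-rich lists at 6.83 and 4.73, and the basal list differs by 0.034 between the group means.

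Other cell types were measured at low levels. The mast cell protease gene Cpa3 fell from 32.5 ± 16.4 to 1.15 ± 1.17 CPM (-4.02, adjusted p = 0.00327) and Car3, abundant in fat and muscle, from 58.8 ± 36.4 to 3.93 ± 2.78 CPM (-3.47, adjusted p = 0.00529). These were the only called genes of the immune and adipocyte lists, in which 2 and 1 members reached the minimum level. The immune list's other tested gene, Epcam, which epidermal Langerhans cells express, had a value of 0.20. The endothelial and mural list, with Cspg4 at -0.49, took 0.00796% ± 0.00220 of counts in WT and 0.00253% ± 0.000500 in p63alphaKO. Merkel and neural markers had Chga at 0.61 and Ncam1 at -0.77 (adjusted p = 0.154 and 0.102). Melanocyte markers had a median of 0.44 over 4 tested genes (camera adjusted p = 0.0675, 0.418 with an estimated correlation), with Dct at 0.76 (adjusted p = 0.0978) and Pmel at 0.29 (adjusted p = 0.634). With 1 library left out the melanocyte median lay between 0.17 and 0.59, and the list was called without WT replicate 3 or p63alphaKO replicate 3 (adjusted p = 0.0269 and 0.0227). Y-linked genes were not called (4 tested, median -0.25, camera adjusted p = 0.892 with the opposite sign), with Ddx3y at -0.32 and Kdm5d at -0.19.

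In all, 13 of the 30 tested lists were called by camera, 9 higher and 4 lower, against 0 with an estimated correlation and 0 by fry for a shift on balance. Fry for change in either direction called 5. These were the fibroblast and dermis list, also called by camera, and the basal, spinous, TGF-beta and hair keratin lists, which camera did not call. Splits of the libraries that mix the genotypes called between 3 and 13 lists by camera. With the dermal score as a covariate, chosen after seeing the data, 0 genes and 5 lists were called, but the score separates the genotypes in every library, so this fit has little left to estimate genotype from. With the members of the lists for other cell types, heat shock and immediate early genes, mitochondrially encoded transcripts and Y-linked genes left out together, likewise chosen later, 93 genes were called, 34 higher and 59 lower.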

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

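The numbers of genes and lists called depended more on the processing than the directions did. With a minimum mean of 50 CPM 36 genes were called, 12 higher and 24 lower. Library weights called 318 (139 higher, 179 lower), DESeq2 on the recovered reads 317 (152 and 165) and edgeR 82 (21 and 61). An adjusted p under 0.1 took in 322 (131 and 191). Upper quartile factors called 133, with 69 higher, TMM factors 112 (47 higher, 65 lower) and quantile normalization 108 (42 and 66), so that 48.1%, 58.0% and 61.1% of calls were lower, against 71.5% of 123 as reported. The other gene counts, among them 116 and 149 with pseudocounts of 0.5 and 5, 110 with no filter and 111 with robust moderation, stayed within 1.5 times the reported one. Leaving out 1 library gave between 37 and 186 changed genes, between 3 and 90 higher and between 34 and 96 lower. Except as said, the cause was not tested. Of the 45 named genes that were called, 21 lost their call with robust moderation, 15 with edgeR, 12 with no filter, 9 with TMM factors, 8 each with upper quartile factors and quantile normalization, and 4 with DESeq2. With a minimum mean of 50 CPM 17 lost it and 9 were not tested. Robust moderation ended the calls of Col1a1 (adjusted p = 0.0826), Acta1 (0.0622), Krt6b (0.0755), Dusp6 (0.0753) and Plet1 (0.291), among others, and Plet1 was also lost with edgeR (0.0810) and DESeq2 (0.135). Of the 45, 13 were called without each library in turn. Lists called were 12 to 16 with a library left out, against 13 as reported. Camera with an estimated correlation called 0 (0 higher, 0 lower), with a lowest adjusted p of 0.291, and fry 0 (0 higher, 0 lower).

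No pairing of libraries by replicate number was seen, though 3 libraries per group are too few to exclude it. Replicate 2 was the female library by Xist in both genotypes. The deviations of same-numbered libraries from their group means had correlations of -0.023, 0.066 and -0.11, and not every library correlated best with its own number. With the replicate number as a block 127 genes were called, and the calls of Fgfr1, Fos, Hspa1a and Egln3 were lost (adjusted p from 0.0567 to 0.0660).

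Of the settings chosen after seeing the data, sex as a covariate gave 100 genes, leaving out Gm42418 142, and leaving out together the lists for other cell types, heat shock and immediate early genes, mitochondrially encoded transcripts and Y-linked genes 93. The last does not show the effect of other cell types alone. Sex as a covariate ended the calls of 7 named genes, Cpa4, Fgfr1, Id2, Fos, Hspa1a, Egln3 and Hba-a2, with unchanged log2 fold changes and adjusted p from 0.0562 to 0.0659. The dermal score as a covariate gave 0 genes (0 higher, 0 lower) and 5 lists, 1 higher and 4 lower. It differed between the genotypes in every library, so the fit has little left to estimate genotype from. There, the median of hemidesmosome genes was -0.33 and that of fibroblast genes -0.065 with camera's direction turned. Under the same covariate Col3a1 was at 0.053, Meg3 at 0.26, Col6a3 at 0.86 and Fgfr1 at 0.17. No other called named gene changed sign in the settings run. The median of the called glycolysis and hypoxia list turned negative without p63alphaKO replicate 1 (-0.057) and without WT replicate 3 (-0.00096). Zeb2, not called as reported, was at 0.26 with the dermal score. Some lists not called as reported were called in other settings: the hair keratin and follicle sheath list in 8 of 22, the p53 family target list in 3 and the basal list in 2 of them, melanocyte markers in 3 of 20, heat shock and immediate early genes in 2 of 21, the Wnt and hair placode list in 1 of 22 and Y-linked genes in 1 of 20. With 1 library left out, medians of other lists not called also moved: p53 family targets from -0.11 to 0.15, interferon response genes from -0.26 to 0.0046, spinous genes from -0.080 to 0.033, desmosome genes from -0.13 to -0.026, and Y-linked genes from -1.73 to 1.34. The same held for cholesterol synthesis genes (-0.12 to 0.0074), the unfolded protein list (-0.17 to 0.0011) and simple epithelial genes (-0.043 to 0.16). Genes named without a call that were called with some library left out include Dsc3, Igfbp2, Cnfn, Crct1, Sprr2e, Sprr1b, Lce3c, Lce1f, Lce1h, Il1a, Epgn, Zeb2, Sox9, Krt79, Slc2a1, Adm, Dct and Hba-a1. Values of genes without a call also moved with 1 library left out. Examples are Ndrg1 (0.51 to 1.07), Igfbp2 (-1.72 to -0.82), Lamb3 (0.33 to 0.74), F11r (0.44 to 0.95) and Crct1 (0.39 to 0.86). Depth limits genes near 10 CPM, where a library holds between 25.7 and 44.8 reads.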

Other observations

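Several called genes lie outside the rule for naming and were chosen here after their values were seen. Ptgs2, which encodes the inducible cyclooxygenase, rose by 2.64 on the log2 scale (adjusted p = 0.00106), the protease-activated receptor gene F2rl1 by 1.32, the heme oxygenase gene Hmox1 by 1.21 and Prdm1, a transcription factor of terminally differentiating keratinocytes, by 0.74. The POU factor gene Pou3f1 fell by 1.64, the connexin gene Gjb5 by 1.33, Tnfrsf19 by 1.24 and the transcription factor gene Nfix by 1.14. None of these belongs to any of the gene lists. Whether their calls hold with a library left out is not given here. Without p63alphaKO replicate 1, 2 or 3, only 6, 6 or 3 higher genes were called in all.

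Embryo sex could be read from the libraries. Xist was at 683 CPM in WT replicate 2 and 473 CPM in p63alphaKO replicate 2 and at most 3.78 CPM in the other 4 libraries, and Ddx3y was at 4.24 and 1.16 CPM in the former and at least 101.7 CPM in the latter. Each genotype thus had 1 female and 2 male libraries by these genes, so its libraries did not all come from the same embryo.

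Explanations for 3 patterns were tested. The tests of a fall inside keratinocytes, of genotype acting on attached dermis, of shared 3' ends, of the granular list, and of dilution for late cornified envelope genes were chosen only after the result was seen. The dermal score rests on 18 tested members of a list of 23, of which 2 (Postn and Vim) also stand in another list and 13 had a mean of at least 10 CPM in p63alphaKO. Its most abundant genes, Col1a2 and Col1a1, were at 1158 ± 518 and 918 ± 440 CPM in WT (n = 3), although Dispase separation is meant to remove dermis.

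The genes lower in p63alphaKO included markers of dermis, muscle and blood. A fall inside keratinocytes is argued against as the cause of the whole pattern, since muscle markers, which keratinocytes do not make, had a median log2 fold change of -2.64. More dermal tissue carried into the WT preparations may account for part of it: the 53 lower genes in no list followed the dermal score within genotypes with a median slope of 0.29, above 0.117, the upper end of the central 95% of 1000 random gene sets of matched level, and 42 of the 53 slopes were positive. The muscle and erythroid lists did not follow it, with median slopes of -0.92 and -0.0056, so this test does not explain their falls. The slope of 0.29 times the score difference of -2.40 gives -0.70, against a median fold change of -1.77 for the 53 genes. The slope has no error estimate here, and these genes were chosen by their difference in the same libraries. How much of their fall the score accounts for is therefore not settled. The random sets also treat genes as independent. The dermal scores of the genotypes did not overlap, the lowest WT score lying 1.25 above the highest p63alphaKO score. An exact permutation test gave p = 0.1, the smallest that 3 against 3 allow. An effect of p63alphaKO on how much dermis stays attached and differences in dissection cannot be told apart, since either would separate the scores by genotype.

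For the higher Trp63 level, a log2 fold change of 0.93 (SE 0.19), 2 technical readings are argued against. Dilution of epidermal RNA by dermal RNA in WT would raise other epidermal genes as much, and the median over 72 tested basal, spinous, granular and desmosome genes was 0.065. A larger basal share would raise basal genes as much, and their median was 0.27 over 19 genes, and between 0.11 and 0.36 with 1 library left out. A different 3' end or read yield of the edited transcript stays open, since the count is per gene. The lookup of 3' ends found 4 annotated coding transcripts that share the most common one, without telling which isoforms they encode. A rise in transcription or stability of the remaining isoforms was not tested.

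For late cornified envelope genes, with a median of 1.17, a rise of all granular and cornified genes by as much is argued against. The granular and cornified list had a median of 0.20, and the member fold changes of the 2 lists differed (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give), though genes are not independent replicates. The small proline-rich list had a median of 1.41 over 9 tested genes, so a rise in part of the cornified layer genes stays open. Dilution by dermal RNA in WT is argued against by the median of 0.065 over the 72 other epidermal genes. A first test of dilution, with the dermal score as a covariate, left the list's median at 1.13 but with a standard error of 1.79 for its mean, and decided nothing. A single library stays open as a cause of much of the size, since the median without WT replicate 3 was 0.59.

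The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 123 genes and the highest of the others 0, so 1 split reached that count. For the lists the real split called 13, and the splits that mix genotypes called 3, 9, 10, 8, 12, 13, 6, 12 and 10. So 2 splits reached a count of 13, and the number of lists called by camera does not set genotype apart from other groupings.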
